A study of Homo sapiens with 27 samples.

How the data were processed

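RNA was measured by sequencing in 27 libraries from 3 human cell lines: THP-1 monocytic leukaemia cells that had been differentiated with PMA, PC-3 prostate carcinoma cells and SW620 colorectal carcinoma cells. Each line was sampled untreated (0 h) and after 3 h and 6 h with 40 µg/ml L-pampo, with 3 libraries in each of the 9 groups. Treatment was added 1 h after a change to fresh medium, per the labels. No treated time point had an untreated sample of the same age, so treatment and time in the fresh medium were not separated. The labels do not say whether the 3 libraries of a group came from separate cultures, so every p-value measures only the spread between these samples.

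Per the submitters' processing notes, total RNA was taken up in TRIzol, stranded mRNA libraries were made with an Illumina TruSeq kit, and reads were trimmed with Trim Galore and cutadapt (listed as version 0.6.10), aligned to GRCh38 with STAR 2.7.10b and quantified with RSEM 1.2.28. The authors deposited 1 table of TPM values for 19456 genes, in which every column could be assigned to its library by name. The deposited TPM columns were checked: they summed to between 955940 and 969007, 0 pairs of libraries were identical, 84 symbols stood on more than 1 line of the table, and 1495 genes were listed at 0 in all libraries. TPM keeps no read depth, so depth per library is unknown and neither counting intervals nor a detection floor could be given. The lowest value of the housekeeping genes was 8.04 TPM, and 0 pairs of gene and line combined a median of at least 20 TPM with a value of 0, so a 0 was read as listed and not as a failed estimate. Transcript length, GC content and coordinates came from GENCODE release 29 on GRCh38 and were available for 19257 genes (98.98%). Length and GC content were medians over the protein-coding transcripts of a gene, so a gene with many short annotated transcripts counted as short.

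TPM was analysed as log2(TPM + 1), on which scale fold changes of genes at low levels are understated. A gene was tested where it reached a TPM of 1 in at least 3 libraries. Linear models were fitted with limma 3.58.1 in R 4.3.3, with eBayes and a mean-variance trend, two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. One model per line (9 libraries) gave 3 h against 0 h, 6 h against 0 h and 6 h against 3 h. One model over all 27 libraries gave the 6 differences between lines in the response to treatment and the 3 differences between untreated lines. The 3 h and 6 h comparisons of a line share their untreated libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for summaries, and matplotlib 3.10.9 for figures.

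Gene groups were tested with camera at a preset correlation between genes of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison with at least 5 measured members. Camera compares a list with all other genes, so a list can be called up while its median falls, where the median of all genes falls further. The comparisons, the tests, the 33 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The 14 lists described were chosen after their results were seen: TLR and RNA sensors and adaptors, neutrophil and monocyte chemokines, inflammatory cytokines, NF-kB target and feedback genes, lymphocyte chemokines, interferon-stimulated genes, MHC class I antigen presentation, cytosolic ribosomal proteins, mitochondrially encoded genes, metallothioneins and NRF2 targets, glycolysis and hypoxia, matrix proteases and invasion, G2 and M phase, and co-stimulatory and checkpoint ligands. Type I and III interferons had too few measured members for a list test and are reported as genes. Of 157 list calls over the comparisons of treated cells and of responses, 11 held with a correlation estimated from the data, and that p is given beside each call. Of the same 157 calls, 111 kept direction and call after scaling.

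The named genes of a treated against untreated comparison were the 8 largest rises and 6 largest falls with an adjusted p under 0.05, a mean of at least 5 TPM in the higher group and libraries that did not overlap between the groups, plus up to 4 members of each list described with the largest log2 fold change, an adjusted p under 0.05 and a mean of at least 2 TPM in the higher group. Differences between responses named the 6 largest in each direction, with a mean of at least 5 TPM in 1 group. TLR1, TLR2, TLR3, TLR6, MYD88, TICAM1, IFIH1, TNF, IL6, CXCL8, IFNB1, CXCL10, ISG15, NFKBIA, TNFAIP3 and CD274, and the 3 most abundant macrophage, intestinal and prostate markers of each line, were always measured. For 6 h against 3 h, the genes already named in the line were used. Some genes that the rule chose are not reported here; none was replaced, and they stayed in every model, count and list. Any other gene is said to have been chosen after its values were seen.

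The other settings chosen in advance were a pseudocount of 0.1 or 5, no filter or a TPM of 5, median-of-ratios scaling factors computed from the TPM values (called scaling in the results), quantile normalization, no mean-variance trend, one model over all libraries, the replicate number as a block, leaving out each library, genes expressed in both lines of a difference, and the set tests fry and camera with an estimated correlation. A further 3 were added after seeing the data: removal of the trends with transcript length and GC content from each library (a spline with 4 degrees of freedom, called trend removal in the results), leaving out a pair of THP-1 6 h libraries that stood apart, and scaling without 1 SW620 6 h library that stood apart. Other splits of the same libraries into groups of the same sizes were counted, with at most 100 drawn (seed 11). The procedure was tested on simulated data with 200 changed genes: at a log2 change of 1, 91.4%, 97.6% and 93.8% were recovered in THP-1, PC-3 and SW620 at 6 h, and at 0.5 31.6%, 72.6% and 50.7%. False calls made up 4.08%, 5.24% and 3.55% of the calls. For a difference between the 6 h responses of PC-3 and SW620, 77.0% were recovered at 1 and 30.3% at 0.5, and 5.67% of calls were false. The simulation changed genes in random directions, with the same SD of a gene at all times and no shift shared by all genes. Its rates therefore do not carry over to comparisons in which most genes moved together.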

Results

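In order to compare how a macrophage-like line and a pair of carcinoma lines respond to L-pampo, a toll-like receptor (TLR) agonist, mRNA levels were measured in THP-1, PC-3 and SW620 cells before treatment and after 3 h and 6 h with 40 µg/ml. Each of the 9 groups held 3 libraries. The chemokines CCL20 and CXCL1 rose in all 3 lines at 3 h. Cytokine transcripts such as IL6 rose in THP-1 and PC-3, and IL6 was listed at 0 in every SW620 library. Interferon-stimulated transcripts such as OASL and IFIT1 rose by far more in PC-3 than in THP-1, whose untreated libraries already held them at high levels. They also rose in SW620. All p-values below are from limma or camera and adjusted by Benjamini-Hochberg. The SD of 3 libraries follows ±, and SE is that of a log2 fold change. Counts of list members were equal when adjusted over the list alone, unless that count is given.

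The composition of the libraries moved with treatment. The median TPM over all listed genes was 4.29 ± 0.0700 in untreated THP-1, 2.90 ± 0.0377 at 3 h and 1.80 ± 0.352 at 6 h. In PC-3 it was 5.67 ± 0.10, 3.63 ± 0.300 and 3.75 ± 0.295. In SW620 it was 4.26 ± 0.0917, 3.65 ± 0.0520 and 3.56 ± 0.410. Mitochondrially encoded transcripts took 9.08 ± 0.546%, 12.7 ± 0.834% and 20.7 ± 3.52% of TPM in THP-1. Cytosolic ribosomal protein transcripts took 4.06 ± 0.227%, 4.96 ± 0.0779% and 6.13 ± 0.455%. The corresponding mitochondrial shares were 13.6 ± 1.37%, 17.6 ± 1.70% and 16.1 ± 3.08% in PC-3. They were 16.4 ± 1.33%, 17.8 ± 0.773% and 16.5 ± 1.29% in SW620. Replicates 2 and 3 of THP-1 at 6 h had median TPM values of 1.64 and 1.55 against 2.20 in replicate 1. Replicate 2 of SW620 at 6 h had 3.11 against a group mean of 3.56.

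**Figure D1:**
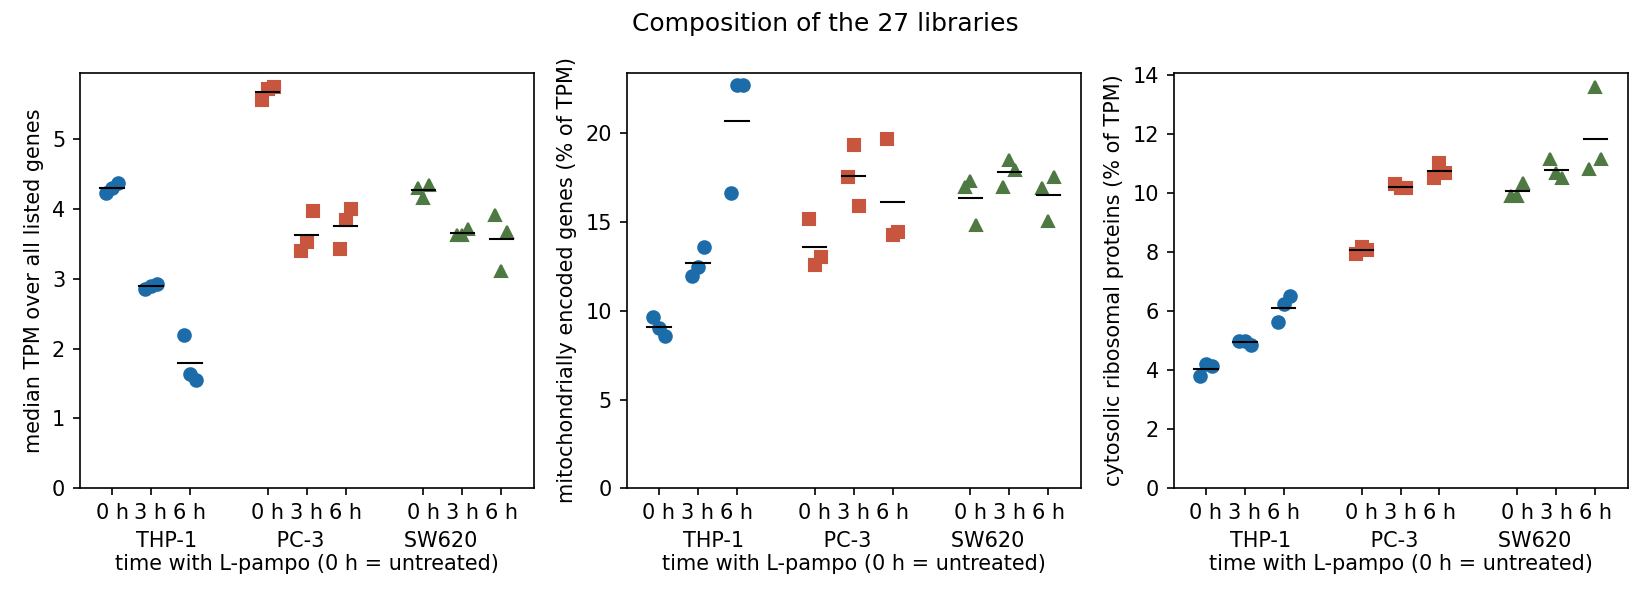
Median TPM over all listed genes and the percent of TPM held by mitochondrially encoded and cytosolic ribosomal protein genes in each library (points) and their group means (lines), by line and time with L-pampo. In THP-1 the median TPM was 4.29 before and 1.80 after 6 h, and the mitochondrial share 9.08% and 20.7%.

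With these shifts, the median log2 fold change of all genes tested against untreated cells was -0.38 at 3 h and -0.89 at 6 h in THP-1, -0.41 and -0.39 in PC-3, and -0.13 and -0.18 in SW620. Values are given as measured, and splits into rises and falls also after median-of-ratios scaling, which removes this shift ("after scaling"). Longer transcripts had lower fold changes in every treated against untreated comparison. Spearman coefficients across genes, which are not independent replicates, were -0.37 and -0.34 in THP-1, -0.42 and -0.40 in PC-3, and -0.33 and -0.39 in SW620. With the genes in 10 equal groups by transcript length, the median in THP-1 at 6 h was -0.67 in the shortest group and -1.30 in the longest.

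**Figure D2:**
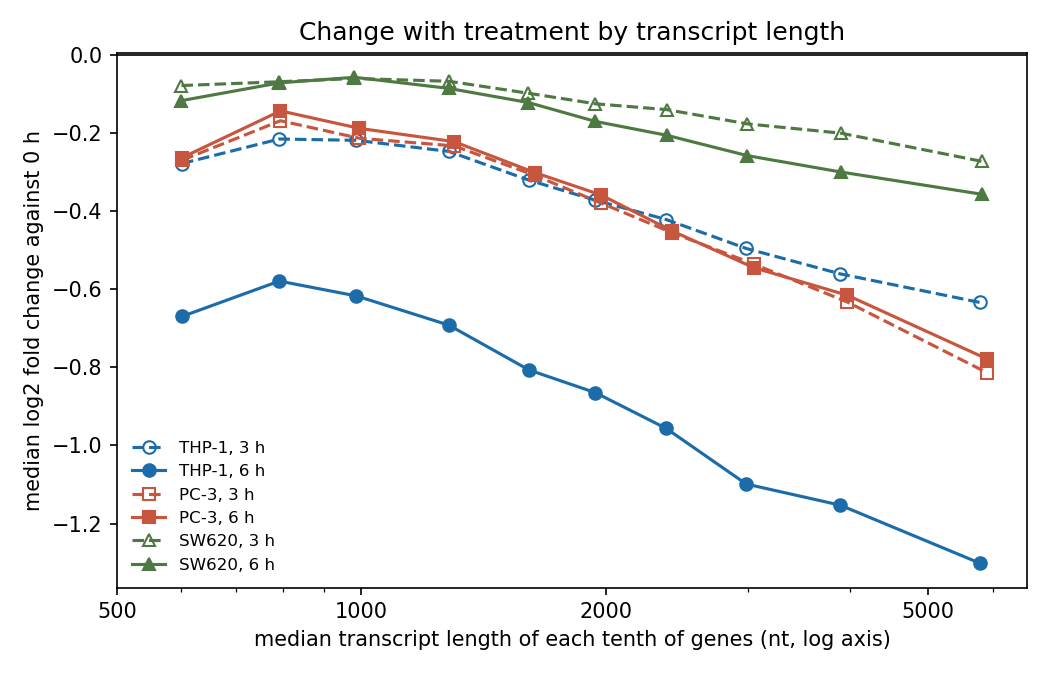
Median log2 fold change against untreated cells of 10 equal groups of genes ordered by transcript length (nt, log axis), for each line at 3 h and 6 h. From the shortest to the longest group the median went from -0.27 to -0.81 in PC-3 at 3 h and from -0.08 to -0.27 in SW620 at 3 h.

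Before treatment, the lines differed in sensors of L-pampo. TLR2, a receptor for bacterial lipopeptides, stood at 281 ± 7.20, 5.24 ± 0.857 and 0.0700 ± 0.0755 TPM in THP-1, PC-3 and SW620 (3 libraries per line). The log2 difference of THP-1 minus PC-3 was 5.51, SE 0.15, adjusted p = 6.8e-21. That of PC-3 minus SW620 was 2.54, SE 0.15, adjusted p = 1.1e-13. TLR3, a receptor for double-stranded RNA, stood at 7.63 ± 0.571, 1.04 ± 0.189 and 0.0967 ± 0.0586 TPM. TLR1, a partner of TLR2, stood at 56.5 ± 2.45, 0.310 ± 0.01 and 0.0167 ± 0.0289 TPM. IFIH1, a cytosolic sensor of double-stranded RNA, stood at 172 ± 5.21, 4.36 ± 0.632 and 4.36 ± 0.722 TPM. The adaptor MYD88 stood at 219 ± 18.6, 44.0 ± 1.79 and 36.7 ± 0.242 TPM. CXCL8, a neutrophil chemokine, stood at 12199 ± 748, 812 ± 23.8 and 11.6 ± 0.758 TPM. CXCL10, which attracts T cells, stood at 87.1 ± 4.04, 0.0233 ± 0.0404 and 0.0600 ± 0.0600 TPM. The macrophage markers LAPTM5, FCER1G and TYROBP reached 2598 ± 71.1, 1658 ± 67.5 and 1194 ± 73.9 TPM in THP-1. The prostate marker HOXB13 reached 49.7 ± 2.12 TPM in PC-3, and the intestinal markers VIL1, AXIN2 and ASCL2 reached 217 ± 5.85, 179 ± 5.42 and 67.3 ± 6.32 TPM in SW620. Markers were not all exclusive: STEAP1, chosen as a prostate marker, stood at 78.3 ± 3.52, 31.7 ± 1.75 and 30.8 ± 0.895 TPM. In total 11274, 11199 and 10069 of 13605 genes differed between untreated THP-1 and PC-3, THP-1 and SW620, and PC-3 and SW620.

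After 3 h with L-pampo, THP-1 cells held more transcript of interferon beta, chemokines and cytokines. IFNB1, which encodes interferon beta, rose (24.5 ± 1.48 against 2.82 ± 0.184 TPM, log2 fold change 2.74, SE 0.11, adjusted p = 6.2e-08; 3 libraries per group). IL6, a cytokine of the acute phase, also rose (299.8 ± 17.4 against 52.3 ± 9.71 TPM, log2 fold change 2.51, SE 0.13, adjusted p = 8.1e-07). ACOD1, the enzyme that makes itaconate in macrophages, rose (58.7 ± 1.36 against 9.31 ± 1.50 TPM, log2 fold change 2.54, adjusted p = 3.8e-07). TNFAIP2, a gene induced by TNF, rose too (567 ± 25.5 against 129 ± 15.9 TPM, log2 fold change 2.13, adjusted p = 7.4e-05), and so did TSLP, a cytokine that acts on dendritic cells (17.6 ± 1.42 against 3.46 ± 0.251 TPM, log2 fold change 2.06, adjusted p = 1.7e-06). CCL4 and its near copy CCL4L2, chemokines for monocytes and other leukocytes, rose by 2.43 and 2.64 on the log2 scale. Reads of these copies can be assigned to either. C11orf96 rose by 2.56, and IFNL1, a type III interferon, stood at 3.24 ± 0.713 against 0.197 ± 0.341 TPM (log2 fold change 1.85). The largest falls included PLEC, which links cytoskeletal filaments (34.9 ± 0.342 against 129 ± 2.39 TPM, log2 fold change -1.86, adjusted p = 3.0e-04). The others were in MACF1, which crosslinks actin and microtubules (-1.57), the receptor NOTCH1 (-1.58), the corepressor TLE3 (-1.60), NKTR (-1.59) and CCDC194 (-1.55). Altogether 6366 of 11605 genes changed, 452 upwards and 5914 downwards. After scaling 3565 changed, 2252 upwards and 1313 downwards.

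Grouped by list, neutrophil and monocyte chemokines rose in THP-1 at 3 h (12 of 17 rose, adjusted p = 3.7e-30, or 0.082 with an estimated correlation). CXCL2 stood at 829 ± 14.4 against 229 ± 34.4 TPM, log2 fold change 1.86, and CXCL3 and CXCL8 rose by 1.30 and 0.63. Of the inflammatory cytokines, 11 of 24 rose, adjusted p = 4.6e-24, or 0.082 with an estimated correlation. Among them TNF stood at 901 ± 64.7 against 265 ± 10.7 TPM, log2 fold change 1.76. The colony-stimulating factors CSF2 and CSF3 rose by 1.87 and 2.02, and IL36G by 1.85. Of the NF-kB target and feedback genes, 14 of 33 rose and 4 fell (21 and 0 after scaling), adjusted p = 9.0e-20, or 0.21 with an estimated correlation. TNIP3, TRAF1 and BIRC3 rose by 1.77, 1.69 and 1.49, and the NF-kB inhibitors NFKBIA and TNFAIP3 by 0.51 and 0.58. Of the lymphocyte chemokines, 3 of 7 rose, adjusted p = 4.6e-05, or 0.15 with an estimated correlation. CCL5 rose by 0.59 and CXCL10 by 0.55. Of the co-stimulatory and checkpoint ligands, 6 of 18 rose and 3 fell (8 and 0 after scaling), adjusted p = 0.00101, or 0.66 with an estimated correlation. IDO1, which degrades tryptophan, rose by 0.98. CD274, which encodes PD-L1, stood at 26.5 ± 0.674 against 25.9 ± 3.80 TPM, log2 fold change 0.04, adjusted p = 0.82.

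Interferon-stimulated genes were not called as a list in THP-1 at 3 h: 3 of 75 rose and 42 fell (3 and 43 adjusted over the list alone, 24 and 14 after scaling), camera adjusted p = 0.48. HELZ2 and PARP10 changed by -1.11 and -0.99. ISG15, a ubiquitin-like antiviral protein, stood at 886 ± 34.0 against 858 ± 13.6 TPM, log2 fold change 0.05, adjusted p = 0.76. TLR3 fell to 4.39 ± 0.307 against 7.63 ± 0.571 TPM, log2 fold change -0.68, adjusted p = 0.0043, and TLR6 changed by -0.64. Cytosolic ribosomal proteins rose as a list (25 of 47 rose, adjusted p = 1.1e-40, or 0.11 with an estimated correlation; RPL38 0.61). Mitochondrially encoded genes did as well (9 of 13 rose, adjusted p = 4.9e-18, or 0.19 with an estimated correlation; MT-ND3 0.91). TWIST1, a transcription factor of mesenchymal cells, rose by 1.03, and VEGFA and MKI67 changed by -1.25 and -1.52.

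After 6 h, the median of all genes in THP-1 had fallen further. IL6 reached 487 ± 50.3 against 52.3 ± 9.71 TPM, log2 fold change 3.21, SE 0.13, adjusted p = 5.2e-08. IFNB1 stood at 26.2 ± 0.112 against 2.82 ± 0.184 TPM, log2 fold change 2.83, adjusted p = 3.2e-08. CXCL10 rose (571 ± 92.3 against 87.1 ± 4.04 TPM, log2 fold change 2.69, SE 0.11, adjusted p = 6.2e-08), together with CXCL11 (2.27) and CXCL9 (1.30), which signal through the same receptor on T cells. CCL8 and CCL2, which attract monocytes, rose by 2.94 and 2.02, CCL4 and CCL4L2 by 2.96 and 3.58, IDO1 by 2.94 and IL36G by 2.78. SNURF stood at 13.1 ± 4.42 against 0.563 ± 0.357 TPM, log2 fold change 3.14, adjusted p = 5.7e-05, and its reads are shared with an overlapping gene. The largest falls were in PLEC (9.74 ± 4.97 against 129 ± 2.39 TPM, log2 fold change -3.69, adjusted p = 4.1e-07) and FN1, which encodes the matrix protein fibronectin (244 ± 90.7 against 1999.8 ± 107 TPM, log2 fold change -3.09, adjusted p = 4.0e-07). Others were in NOTCH1 (-3.18), CEMIP, which degrades hyaluronan (-3.11), TNRC18 (-3.10) and MACF1 (-3.0). In total 9936 of 11605 genes changed, 633 upwards and 9303 downwards. After scaling 7361 changed, 3847 upwards and 3514 downwards.

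Of the neutrophil and monocyte chemokines, 14 of 17 rose and 2 fell (17 and 0 after scaling), adjusted p = 4.8e-31, or 0.056 with an estimated correlation. CXCL8 stood at 26207 ± 2074 against 12199 ± 748 TPM, log2 fold change 1.10 (-0.05 after quantile normalization). Of the inflammatory cytokines, 12 of 24 rose and 6 fell (19 and 1 after scaling), adjusted p = 2.1e-18, or 0.062 with an estimated correlation. TNF stood at 431 ± 84.1 against 265 ± 10.7 TPM, log2 fold change 0.69. CSF2 rose by 2.18, and CSF1, a macrophage growth factor, changed by -1.74. Of the lymphocyte chemokines, 4 of 7 rose and 1 fell (5 and 0 after scaling), adjusted p = 3.9e-09, or 0.056 with an estimated correlation. CXCL16 was the exception with -1.18. The NF-kB target and feedback genes were called up (camera adjusted p = 0.0057, or 0.99 with an estimated correlation). Their median was -0.48, however, and 6 of 33 rose and 20 fell (20 and 3 after scaling). TNIP3 rose by 1.71, while ICAM1, a leukocyte adhesion molecule, NFKB2 and PLAU, the urokinase protease, changed by -1.66, -1.37 (0.20 after trend removal) and -1.91. TNFAIP3 changed by -0.87 (0.17 after scaling) and NFKBIA by -0.37 (0.68 after scaling, 0.48 after trend removal). The NFKBIA call was lost without 6 h replicate 2 or 3 (adjusted p = 0.058 each), and the list call without 6 h replicate 1 (adjusted p = 0.23). The interferon-stimulated genes were called up in the same way (camera adjusted p = 0.025, or 0.99 with an estimated correlation). Their median was -0.50, and 9 of 75 rose and 49 fell (49 and 8 after scaling). This call was also lost without 6 h replicate 1 (adjusted p = 0.56). HELZ2 changed by -2.16, OAS3 by -1.59 and ADAR by -1.57. ISG15 stood at 980.0 ± 229 against 858 ± 13.6 TPM, log2 fold change 0.17, adjusted p = 0.23.

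Ribosomal proteins rose in THP-1 at 6 h (38 of 47 rose and 2 fell, adjusted p = 3.3e-55, or 0.056 with an estimated correlation), with RPL38 at 1.37. Mitochondrially encoded genes rose as well (13 of 13 rose, adjusted p = 4.8e-31, or 0.062 with an estimated correlation), with MT-ND3 at 1.83. Of the metallothioneins and NRF2 targets, 8 of 19 rose and 8 fell (13 and 2 after scaling), adjusted p = 6.2e-06, or 0.29 with an estimated correlation. MT2A and MT1X rose by 1.82 and 1.60, and SLC30A1 changed by -1.80. Of the co-stimulatory and checkpoint ligands, 7 of 18 rose and 9 fell (11 and 5 after scaling), adjusted p = 3.3e-05, or 0.55 with an estimated correlation. CD274 rose by 0.59. ICOSLG, VSIR and CD276 changed by -1.86, -1.73 (0.04 after trend removal) and -1.50. Sensors and adaptors were not called (25 of 28 fell (12 and 4 after scaling), camera adjusted p = 0.797). TLR2 changed by -1.09 and CD14 by -1.38. MYD88 changed by -0.49 (0.02 after quantile normalization, 0.56 after scaling, 0.59 after trend removal) and IFIH1 by -0.54 (0.06 after quantile normalization, 0.51 after scaling, 0.48 after trend removal). TLR3 stood at 7.89 ± 1.72 against 7.63 ± 0.571 TPM, log2 fold change 0.03, adjusted p = 0.87. Matrix protease genes (1 of 26 rose and 24 fell (7 and 11 after scaling), adjusted p = 0.32) included MMP9, a gelatinase (491 ± 251 against 2269 ± 71.5 TPM, log2 fold change -2.32), and MMP14 (-2.15). Glycolysis and hypoxia genes were not called (26 of 28 fell (11 and 12 after scaling), adjusted p = 0.066), with VEGFA at -2.18. Neither were G2 and M phase genes (1 of 30 rose and 26 fell (11 and 8 after scaling), adjusted p = 0.58), with MKI67 at -2.42. MHC class I genes were not called either (1 of 20 rose and 17 fell (6 and 6 after scaling), adjusted p = 0.82). Among them TAPBP, a peptide-loading factor, changed by -1.70.

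Between 3 h and 6 h in THP-1, CXCL10 rose to 571 ± 92.3 against 128 ± 8.27 TPM, log2 fold change 2.13, SE 0.11, adjusted p = 2.8e-06. CXCL11 rose by 1.76, CCL8 by 2.71, CCL2 by 1.56 and IDO1 by 1.96. TNFAIP2 fell to 169 ± 64.9 against 567 ± 25.5 TPM, log2 fold change -1.81, adjusted p = 1.1e-04. TRAF1 changed by -1.16, TNF by -1.08, TNFAIP3 by -1.46, CXCL2 by -0.60 (0.01 after scaling) and CXCL8 by 0.48 (-0.08 after quantile normalization). IFNB1 stood at 26.2 ± 0.112 against 24.5 ± 1.48 TPM, log2 fold change 0.09, adjusted p = 0.45. TLR3 rose by 0.71. Of the NF-kB targets, 1 of 33 rose and 27 fell (5 and 16 after scaling), adjusted p = 0.014, or 0.96 with an estimated correlation. Interferon-stimulated genes were called up relative to all genes (adjusted p = 2.5e-07, or 0.96 with an estimated correlation), with a median of -0.11. Of these, 9 of 75 rose and 26 fell (7 and 24 adjusted over the list alone, 53 and 3 after scaling). Neutrophil and monocyte chemokines were called up (10 of 17 rose and 6 fell (12 and 0 after scaling), adjusted p = 4.9e-13, or 0.15 with an estimated correlation). So were lymphocyte chemokines (3 of 7 rose and 1 fell (5 and 0 after scaling), adjusted p = 1.1e-08, or 0.14 with an estimated correlation). Mitochondrially encoded genes were called up too (13 of 13 rose, adjusted p = 1.6e-28, or 0.14 with an estimated correlation). Glycolysis and hypoxia genes were called down (27 of 28 fell (2 and 9 after scaling), adjusted p = 0.0045, or 0.96 with an estimated correlation). In total 7840 genes changed, 378 upwards and 7462 downwards. After scaling 5085 changed, 2711 upwards and 2374 downwards.

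In PC-3 at 3 h, IFIT2 and IFIT1, which bind viral RNA, rose. IFIT2 reached 159 ± 12.2 against 4.19 ± 0.444 TPM, log2 fold change 4.95, SE 0.08, adjusted p = 1.2e-13 (3 libraries per group). IFIT1 reached 47.1 ± 4.36 against 1.63 ± 0.230 TPM, log2 fold change 4.19, SE 0.10, adjusted p = 3.0e-12. OASL, related to the enzymes that activate RNase L, reached 54.2 ± 5.53 against 1.84 ± 0.125 TPM, log2 fold change 4.28, adjusted p = 1.2e-12. IFIT3 rose by 3.27. IFNB1 was listed at 0 in the 3 untreated libraries and at 10.5, 6.46, 8.75 TPM in the treated ones (adjusted p = 5.4e-08). IFNL1 was listed at 0 and at 2.10, 1.96, 3.86 TPM (adjusted p = 5.9e-06). IL6 rose (925 ± 106 against 223 ± 18.4 TPM, log2 fold change 2.04, SE 0.08, adjusted p = 2.0e-09), as did CXCL8 (3168 ± 167 against 812 ± 23.8 TPM, log2 fold change 1.96, SE 0.04, adjusted p = 3.0e-12). ACOD1 rose by 2.46 and PMAIP1, which encodes the pro-apoptotic protein NOXA, by 2.35. SYNJ2BP-COX16, whose reads overlap other genes, changed by 2.10. The largest falls were in AHNAK, a very large scaffold protein (32.4 ± 7.57 against 186 ± 9.02 TPM, log2 fold change -2.51, adjusted p = 1.3e-08). Others were in PLEC (-2.24), SMG1, a kinase of nonsense-mediated decay (-2.21), DST (-2.17), the mucin MUC5B (-2.13) and the proliferation marker MKI67 (-2.08). In total 8324 of 11892 genes changed, 806 upwards and 7518 downwards. After scaling 6577 changed, 3555 upwards and 3022 downwards.

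Of the interferon-stimulated genes, 22 of 67 rose and 19 fell (21 and 18 adjusted over the list alone, 40 and 5 after scaling) in PC-3 at 3 h, adjusted p = 1.0e-14, or 0.201 with an estimated correlation. ISG15 stood at 246 ± 16.8 against 138 ± 4.5 TPM, log2 fold change 0.83. Of the neutrophil and monocyte chemokines, 8 of 8 rose, adjusted p = 2.8e-18, or 0.058 with an estimated correlation. CCL2 rose by 1.65, CXCL2 by 1.30 and CCL20, which attracts dendritic cells and T cells, by 1.29. Of the inflammatory cytokines, 9 of 18 rose and 3 fell (13 and 0 after scaling), adjusted p = 4.3e-11, or 0.11 with an estimated correlation. IL1B stood at 247 ± 23.1 against 68.3 ± 1.65 TPM, log2 fold change 1.83 and CSF2 at 174 ± 4.31 against 53.3 ± 3.00 TPM, log2 fold change 1.69. Of the NF-kB target and feedback genes, 11 of 32 rose and 12 fell (22 and 2 after scaling), adjusted p = 2.7e-08, or 0.22 with an estimated correlation. NFKBIZ, PTX3, NFKBIA and TNFAIP3 rose by 1.31, 1.27, 1.08 and 0.70. Of the lymphocyte chemokines, 2 of 5 rose and 2 fell (3 and 0 after scaling), adjusted p = 0.0071, or 0.11 with an estimated correlation. CXCL10 stood at 3.53 ± 0.495 against 0.0233 ± 0.0404 TPM. The RNA sensors RIGI and IFIH1 rose by 1.34 and 1.05, while MAVS, their adaptor, and TRAF6 changed by -1.14 (0.05 after trend removal) and -0.69. Of the sensors as a list, 3 of 20 rose and 11 fell (6 and 1 after scaling), camera adjusted p = 0.43. TLR2 stood at 4.96 ± 1.44 against 5.24 ± 0.857 TPM, log2 fold change -0.08, adjusted p = 0.72. MYD88 changed by -0.28 (0.08 after quantile normalization, 0.17 after scaling, 0.16 after trend removal). TNF stood below the filter at 0.910 ± 0.286 against 0.0867 ± 0.0850 TPM.

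Ribosomal proteins rose in PC-3 at 3 h (45 of 47 rose, adjusted p = 2.3e-55, or 0.054 with an estimated correlation; RPL38 0.66). So did mitochondrially encoded genes (8 of 13 rose (7 adjusted over the list alone), adjusted p = 6.6e-09, or 0.28 with an estimated correlation), although not after quantile normalization (adjusted p = 0.92). Among matrix and cell cycle genes, TNC, a matrix glycoprotein, ITGA2 and CENPE changed by -1.55, -1.36 and -1.71, and the glycolysis enzyme HK2 by -1.17.

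After 6 h, the largest rises in PC-3 included interferon-stimulated transcripts. OASL reached 294 ± 17.1 against 1.84 ± 0.125 TPM, log2 fold change 6.70, SE 0.09, adjusted p = 6.3e-15, and IFIT1 92.3 ± 3.22 against 1.63 ± 0.230 TPM, log2 fold change 5.15, adjusted p = 2.6e-13. IFI44, RSAD2 (the antiviral enzyme viperin) and ZC3HAV1 (an antiviral zinc finger protein) rose by 4.14, 3.93 and 2.98. IFIT2 and IFIT3 rose by 4.78 and 4.03. ISG15 reached 544 ± 58.1 against 138 ± 4.5 TPM, log2 fold change 1.96, adjusted p = 6.3e-10. The sensors RIGI and IFIH1 rose by 2.89 and 1.82. IFNB1 was listed at 0.720, 1.67, 1.18 TPM, against 0 before treatment (adjusted p = 1.5e-04). IFNL1 was listed at 2.04, 1.34, 2.63 against 0 (adjusted p = 1.7e-05). The largest falls included PLEC (-2.54), MUC5B (-2.43), AHNAK (-2.39), the cadherin FAT1 (-2.22) and BCL9L (-2.20). In total 8255 of 11892 genes changed, 1022 upwards and 7233 downwards. After scaling 6824 changed, 3679 upwards and 3145 downwards.

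As a list, 49 of 67 rose and 5 fell of the interferon-stimulated genes in PC-3 at 6 h, adjusted p = 3.2e-44, or 0.061 with an estimated correlation. Of the neutrophil and monocyte chemokines, 5 of 8 rose, adjusted p = 9.7e-08, or 0.16 with an estimated correlation. CXCL8 stood at 1955 ± 12.7 against 812 ± 23.8 TPM, log2 fold change 1.27, and CCL20 rose by 1.32. Of the inflammatory cytokines, 6 of 18 rose and 4 fell (12 and 2 after scaling), adjusted p = 1.2e-04, or 0.38 with an estimated correlation. IL6 stood at 688 ± 46.9 against 223 ± 18.4 TPM, log2 fold change 1.62. IL1B rose by 0.83, and CSF1 and LIF changed by -0.96 and -0.89. The NF-kB targets were not called (4 of 32 rose and 17 fell (11 and 5 after scaling), camera adjusted p = 0.91). BCL2A1 rose by 0.92, PLAU and REL changed by -1.14 and -1.04. NFKBIA stood at 285 ± 26.8 against 260.4 ± 6.74 TPM, log2 fold change 0.13, adjusted p = 0.085. TNFAIP3 stood at 30.4 ± 2.03 against 34.1 ± 2.42 TPM, log2 fold change -0.16 (0.25 after quantile normalization, 0.28 after scaling), adjusted p = 0.12. Of the lymphocyte chemokines, 2 of 5 rose and 1 fell (3 and 0 after scaling), adjusted p = 0.011, or 0.16 with an estimated correlation. CXCL10 stood at 3.73 ± 0.202 against 0.0233 ± 0.0404 TPM and CXCL11 at 3.62 ± 0.916 against 0.113 ± 0.115 TPM. Ribosomal proteins were called up (44 of 47 rose, adjusted p = 7.6e-50, or 0.061 with an estimated correlation). So were mitochondrially encoded genes (4 of 13 rose, adjusted p = 2.8e-05, or 0.59 with an estimated correlation), although with quantile normalization their direction turned (adjusted p = 0.74). Metallothioneins and NRF2 targets were also called up (8 of 18 rose and 8 fell (11 and 3 after scaling), adjusted p = 0.0057, or 0.15 with an estimated correlation). MHC class I genes were not called (5 of 21 rose and 10 fell (8 and 3 after scaling), adjusted p = 0.081). B2M rose by 0.61 and TAP2 changed by -0.75 (0.06 after trend removal). Prostaglandin and eicosanoid synthesis and pyroptosis and necroptosis were also called up (adjusted p = 0.0083 and 0.021, or 0.25 and 0.43 with an estimated correlation). The next 5 lists were not called. Of the matrix genes, 3 of 23 rose and 16 fell (3 and 17 adjusted over the list alone, 5 and 10 after scaling), adjusted p = 0.47. The collagenase MMP13 rose by 1.30, and LAMB3 changed by -1.30. Of the glycolysis and hypoxia genes, 5 of 27 rose and 16 fell (13 and 7 after scaling), adjusted p = 0.96. Of the G2 and M phase genes, 4 of 30 rose and 15 fell (16 and 4 after scaling), adjusted p = 0.55. Of the co-stimulatory ligands, 6 of 12 fell (5 adjusted over the list alone, 3 and 1 after scaling), adjusted p = 0.64. Of the sensors, 2 of 20 rose and 12 fell (6 and 2 after scaling), adjusted p = 0.55. TLR2 stood at 4.05 ± 1.29 against 5.24 ± 0.857 TPM, log2 fold change -0.32, adjusted p = 0.17. MYD88 stood at 42.1 ± 1.23 against 44.0 ± 1.79 TPM, log2 fold change -0.06 (0.28 after quantile normalization, 0.38 after scaling, 0.40 after trend removal), adjusted p = 0.44.

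Between 3 h and 6 h in PC-3, IFI44 rose to 101 ± 9.98 against 16.8 ± 2.03 TPM, log2 fold change 2.52, SE 0.10, adjusted p = 1.3e-08. OASL rose by 2.42, RSAD2 by 2.28, RIGI by 1.55 and ISG15 by 1.14. IFNB1 fell from 8.57 to 1.19 TPM (log2 fold change -2.13, adjusted p = 1.2e-05) and CSF2 to 57.1 ± 5.95 against 174 ± 4.31 TPM, log2 fold change -1.59, adjusted p = 4.3e-08. The pentraxin PTX3 changed by -1.42, CXCL2 by -1.19, IL1B by -1.01 and NFKBIA by -0.96. Of the interferon-stimulated genes, 45 of 67 rose and 1 fell (56 and 1 adjusted over the list alone), adjusted p = 1.8e-65, or 0.045 with an estimated correlation. Of the NF-kB targets, 1 of 32 rose and 14 fell (2 and 19 adjusted over the list alone), adjusted p = 1.3e-21, or 0.0796 with an estimated correlation. Of the cytokines, 8 of 18 fell (1 and 10 adjusted over the list alone), adjusted p = 7.3e-11, or 0.13 with an estimated correlation. Of the neutrophil and monocyte chemokines, 5 of 8 fell, adjusted p = 4.2e-16, or 0.0796 with an estimated correlation. MHC class I genes were called up (2 of 21 rose (4 adjusted over the list alone), adjusted p = 0.0016, or 0.77 with an estimated correlation). In total 233 of 11892 genes changed, 136 upwards and 97 downwards. After scaling 415 changed, 195 upwards and 220 downwards.

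**Figure D3:**
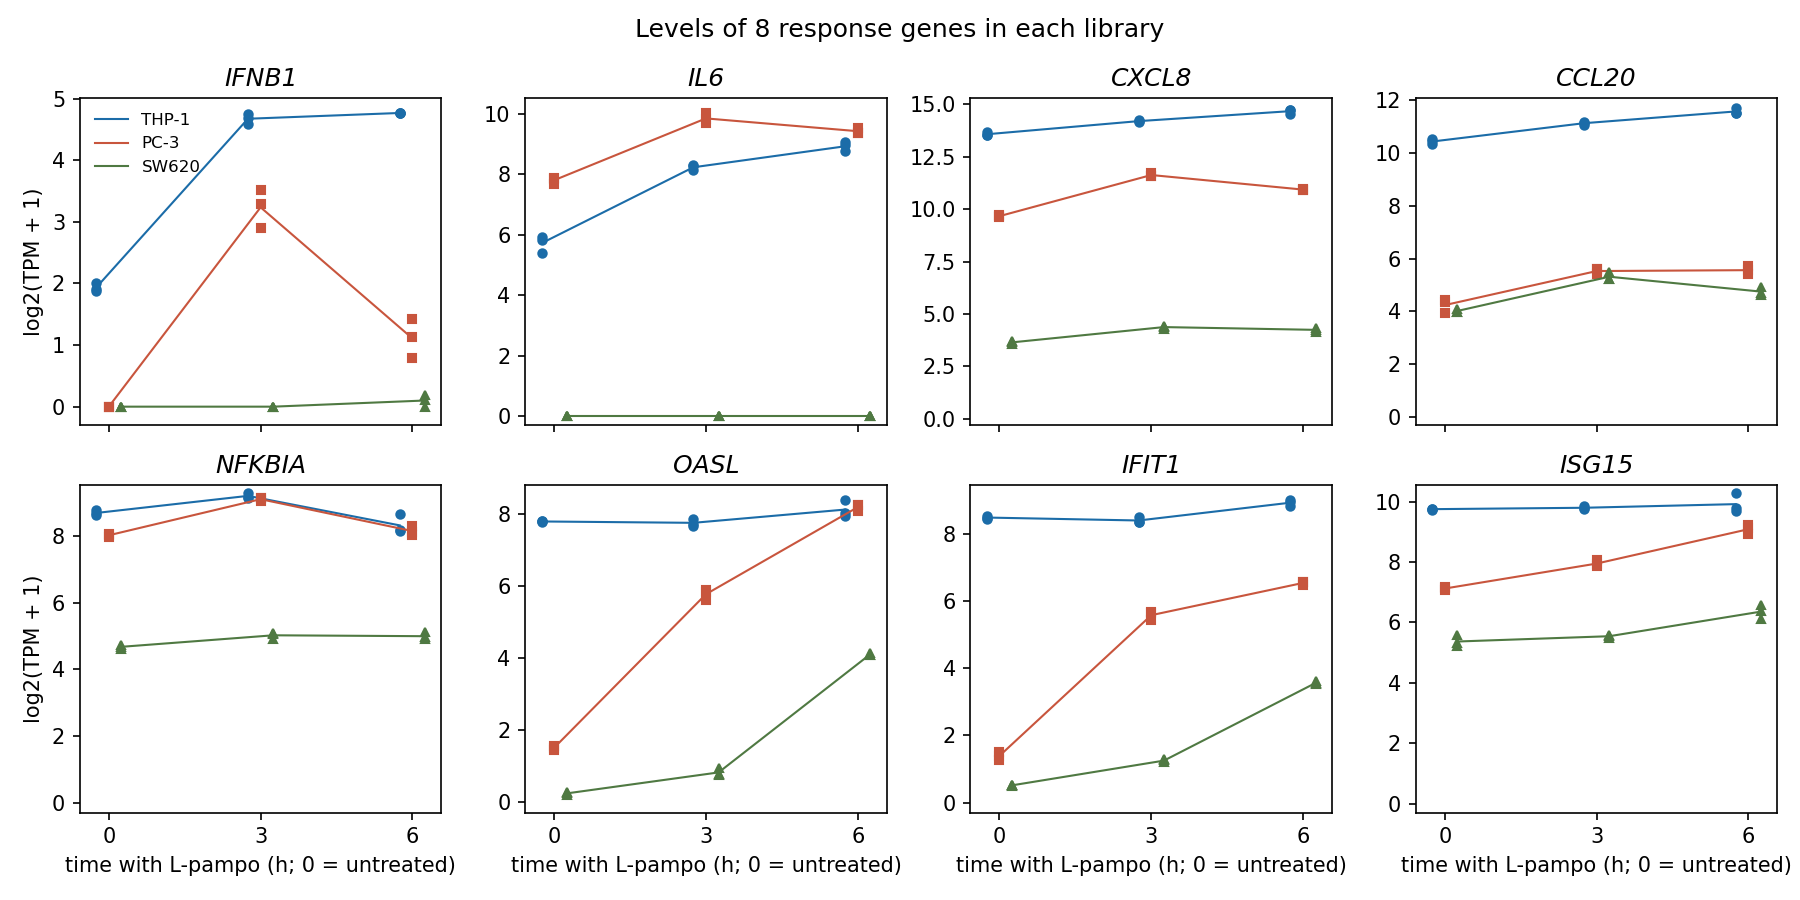
Levels of IFNB1, IL6, CXCL8, CCL20, NFKBIA, OASL, IFIT1 and ISG15 as log2(TPM + 1) in each library (points) and as group means (lines), against hours with L-pampo (0 h untreated). OASL went from 1.84 to 294 TPM in PC-3 over 6 h and from 0.177 to 16.3 TPM in SW620, and stood at 223 and 283 TPM in THP-1.

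In SW620 at 3 h, 7 genes rose, among them chemokines and IFIT2. CCL20 rose (38.9 ± 4.00 against 15.2 ± 0.560 TPM, log2 fold change 1.29, SE 0.11, adjusted p = 8.8e-05; 3 libraries per group), as did CXCL1 (18.9 ± 0.594 against 9.65 ± 0.739 TPM, log2 fold change 0.91, SE 0.10, adjusted p = 0.0029). CXCL8 rose as well (19.8 ± 1.15 against 11.6 ± 0.758 TPM, log2 fold change 0.73, SE 0.10, adjusted p = 0.012). IFIT2 rose (3.46 ± 0.0404 against 0.380 ± 0.121 TPM, log2 fold change 1.69, adjusted p = 6.9e-05). TIGAR, a regulator of glycolysis, also rose (26.8 ± 0.481 against 18.9 ± 1.45 TPM, log2 fold change 0.48, adjusted p = 0.046). The largest falls were in AKAP9, a scaffold of the centrosome and Golgi (4.64 ± 0.813 against 12.5 ± 1.45 TPM, log2 fold change -1.27, adjusted p = 0.012). Others were in SYNE2, which links the nucleus to the cytoskeleton (-1.18), ANKRD36C (-1.10), DST (-0.99), ZNF292 (-0.96) and KRTAP3-2 (-0.94). Of the neutrophil and monocyte chemokines, 3 of 8 rose (6 adjusted over the list alone), adjusted p = 1.0e-15, or 0.069 with an estimated correlation. Of the interferon-stimulated genes, 3 of 50 rose (4 and 2 adjusted over the list alone), adjusted p = 0.0069, or 0.77 with an estimated correlation. This call was lost without 3 h replicate 3 (adjusted p = 0.063). For NF-kB targets no member of 28 passed the limma test (5 rose and 1 fell at an unadjusted p under 0.05) (3 adjusted over the list alone), with adjusted p = 9.6e-04, or 0.53 with an estimated correlation. TNFAIP3 stood at 6.40 ± 1.02 against 4.00 ± 0.381 TPM, log2 fold change 0.56, adjusted p = 0.064. NFKBIA stood at 31.6 ± 1.95 against 24.6 ± 1.17 TPM, log2 fold change 0.35, adjusted p = 0.066. TLR2, TLR3, TNF and CD274 stayed below the filter, at 0.0267, 0.0800, 0.310 and 0.577 TPM. IL6 and IFNB1 were listed at 0 before and after. Altogether 116 of 11458 genes changed, 7 upwards and 109 downwards. After scaling 100 changed, 32 upwards and 68 downwards. The number rested on every library: it was 4, 5 and 3 without untreated replicates 1, 2 and 3. It was 4, 3 and 12 without replicates 1, 2 and 3 of 3 h. CCL20, CXCL1 and IFIT2 passed in each of these fits. Without any 1 library, calls were lost for CXCL8 (adjusted p = 0.055 to 0.082), TIGAR (0.12 to 0.18) and KRTAP3-2 (0.086 to 0.17). They were also lost for ZNF292 and DST without untreated replicates 1, 2 or 3 or 3 h replicates 1 or 2. Their adjusted p was 0.099 to 0.15 and 0.0799 to 0.11. The same held for AKAP9 without untreated replicates 2 or 3 or 3 h replicates 1 or 2 (adjusted p = 0.068 to 0.101), SYNE2 without untreated replicates 1 or 3 or 3 h replicates 1 or 2 (adjusted p = 0.072 to 0.12) and ANKRD36C without untreated replicates 1 or 3 or 3 h replicate 2 (adjusted p = 0.053 to 0.063).

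After 6 h, a minority of interferon-stimulated genes rose in SW620 cells. OASL rose (16.3 ± 0.369 against 0.177 ± 0.0252 TPM, log2 fold change 3.88, SE 0.12, adjusted p = 1.2e-09), as did IFIT2 (15.4 ± 1.71 against 0.380 ± 0.121 TPM, log2 fold change 3.57, adjusted p = 3.0e-09). So did IFIT1 (10.8 ± 0.379 against 0.427 ± 0.0231 TPM, log2 fold change 3.05, adjusted p = 5.1e-09) and IFIT3 (18.6 ± 2.71 against 2.11 ± 0.110 TPM, log2 fold change 2.64, adjusted p = 5.4e-08). RIGI and IFIH1 rose by 1.42 and 0.63. ISG15 stood at 81.5 ± 12.5 against 40.5 ± 5.77 TPM, log2 fold change 0.99, adjusted p = 0.00198. CXCL10 stood at 2.35 ± 0.586 against 0.0600 ± 0.0600 TPM, log2 fold change 1.64, adjusted p = 2.8e-04. BIRC3, an inhibitor of apoptosis that NF-kB induces, rose by 0.81 and PLGRKT, a plasminogen receptor, by 0.73. CCL20, CXCL8 and CXCL1 rose by 0.73, 0.60 and 0.54. The largest falls included PLEC (25.1 ± 6.13 against 55.7 ± 3.61 TPM, log2 fold change -1.14, adjusted p = 0.00198). Others were in the actin crosslinker FLNA (-1.05), the spectrin SPTBN1 (-1.08) and CENPS-CORT (-1.15), whose reads overlap other genes. In total 2709 of 11458 genes changed, 250 upwards and 2459 downwards. After scaling 1570 changed, 914 upwards and 656 downwards. Without untreated replicates 1, 2 and 3 the count was 579, 1093 and 511.

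Of the interferon-stimulated genes, 12 of 50 rose and 3 fell (17 and 1 after scaling) in SW620 at 6 h, adjusted p = 4.0e-15, or 0.23 with an estimated correlation. Of the neutrophil and monocyte chemokines, 5 of 8 rose, adjusted p = 1.3e-09, or 0.23 with an estimated correlation. Of the NF-kB targets, 2 of 28 rose and 3 fell (2 and 1 adjusted over the list alone, 6 and 0 after scaling), adjusted p = 0.0058, or 0.35 with an estimated correlation, with NFKBIA at 0.32. Ribosomal proteins rose (18 of 47 rose (27 adjusted over the list alone), adjusted p = 2.9e-30, or 0.296 with an estimated correlation; RPL27 0.50). Mitochondrially encoded genes were not called (2 of 13 rose and 1 fell (2 and 0 after scaling), adjusted p = 0.061). Neither were matrix genes (5 of 16 fell (6 adjusted over the list alone, 1 and 3 after scaling), adjusted p = 0.55; TNC -0.94). Nor were G2 and M phase genes (2 of 30 rose and 6 fell (3 and 1 after scaling), adjusted p = 0.87; MKI67 -0.87). Glycolysis and hypoxia genes (11 of 29 fell (13 adjusted over the list alone), adjusted p = 0.19; HK2 -0.54) and sensors (2 of 17 rose and 2 fell (2 and 0 after scaling), adjusted p = 0.29) were not called either. Calls at 6 h were lost without untreated replicates 1, 2 or 3 for NFKBIA (adjusted p = 0.057 to 0.103) and RPL27 (0.057 to 0.071). They were lost as well for IFIH1 without untreated replicate 2 (adjusted p = 0.052) and CENPS-CORT without untreated replicates 2 or 3 or 6 h replicate 1 (adjusted p = 0.095 to 0.13).

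Between 3 h and 6 h in SW620, 9 genes changed, all upwards. OASL rose most (16.3 ± 0.369 against 0.767 ± 0.134 TPM, log2 fold change 3.29, SE 0.12, adjusted p = 9.3e-09). The others were IFIT1 (2.32), IFIT3 (2.13), IFIT2 (1.87), RIGI (1.52), CXCL10 (1.18), ISG15 (0.82), MX1, an antiviral GTPase (1.06), and PLAAT4, listed at 0 at 3 h and at 1.50, 1.86, 1.50 TPM at 6 h. MX1 and PLAAT4 were chosen after their values were seen. Calls were lost for CXCL10 without 3 h replicate 1 (adjusted p = 0.079) and ISG15 without 3 h replicates 1, 2 or 3 or 6 h replicates 1 or 2 (adjusted p = 0.064 to 0.16). Of the interferon-stimulated genes, 7 of 50 rose (13 adjusted over the list alone), adjusted p = 1.7e-25, or 0.22 with an estimated correlation. CCL20, CXCL1 and CXCL8 stood at 26.0 ± 3.01 against 38.9 ± 4.00 TPM, 14.5 ± 1.22 against 18.9 ± 0.594 TPM and 18.0 ± 1.26 against 19.8 ± 1.15 TPM. These did not pass the test. After scaling 10 genes changed, and without replicate 1 of 6 h the count was 5.

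**Figure D4:**
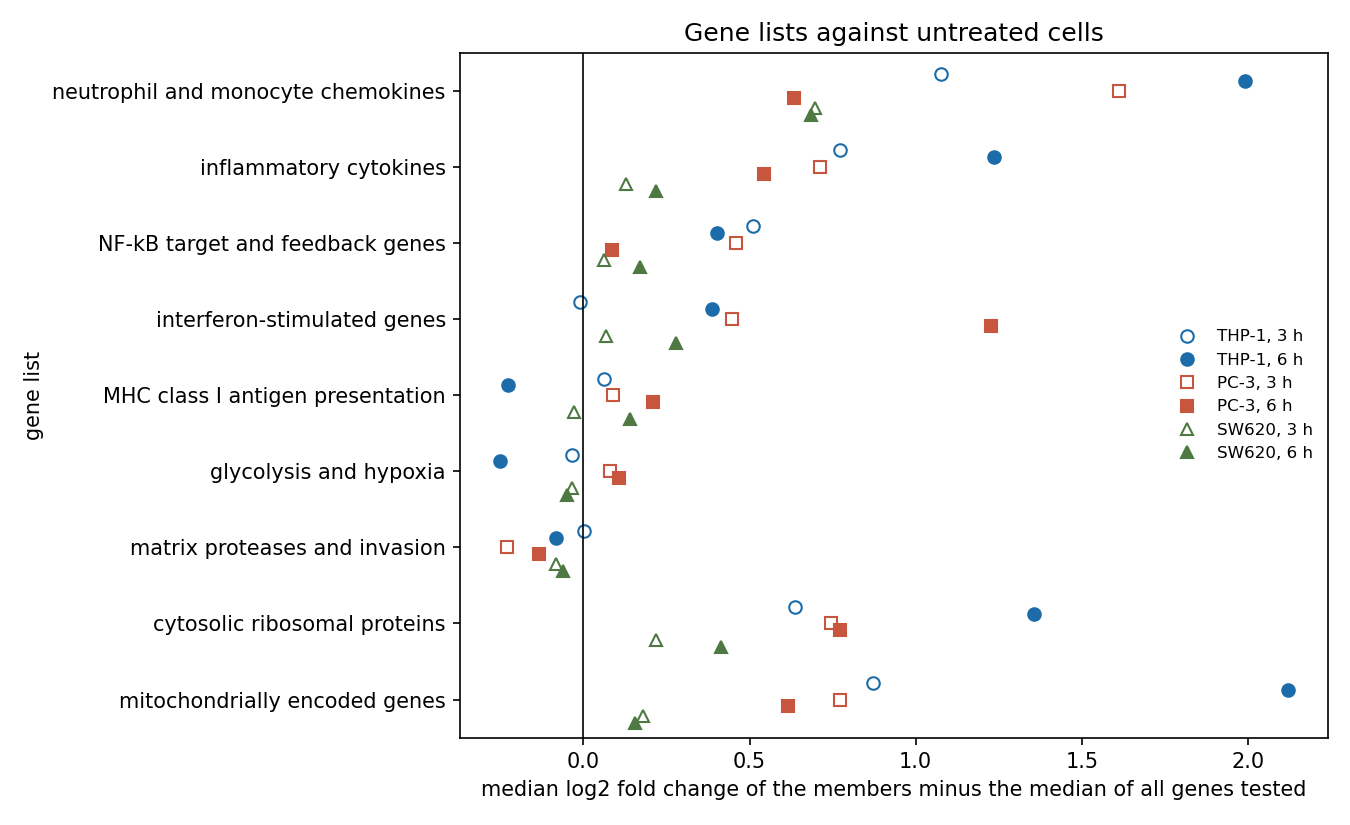
Median log2 fold change of the measured members of 9 gene lists minus the median of all genes tested, for each line at 3 h (open) and 6 h (filled) against untreated cells. Interferon-stimulated genes reached 1.23 in PC-3 at 6 h, against 0.39 in THP-1 and 0.28 in SW620, and neutrophil and monocyte chemokines 1.99 in THP-1, 0.63 in PC-3 and 0.68 in SW620.

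Whether the lines responded differently was tested directly. Interferon-stimulated genes responded less in THP-1 than in PC-3. At 3 h, 25 of 75 were lower (33 adjusted over the list alone) (adjusted p = 8.8e-22, or 0.57 with an estimated correlation). At 6 h, 1 of 75 were higher and 66 were lower (1 and 67 adjusted over the list alone, 8 and 42 after scaling) (adjusted p = 4.7e-17, or 0.21 with an estimated correlation). The OASL response in THP-1 minus that in PC-3 was -4.31, SE 0.14, adjusted p = 2.3e-17 at 3 h and -6.37, SE 0.14, adjusted p = 7.5e-21 at 6 h. Untreated levels were 223 ± 3.38 TPM in THP-1 and 1.84 ± 0.125 TPM in PC-3. CXCL8 also responded less in THP-1 at 3 h (-1.33, SE 0.09, adjusted p = 3.8e-10), and TNF more (0.96, SE 0.20, adjusted p = 0.0022). The IFNB1 difference (THP-1 minus PC-3) was -0.50, -0.08 after scaling, SE 0.18, adjusted p = 0.104 at 3 h. At 6 h it was 1.73, 2.72 after scaling, SE 0.18, adjusted p = 1.2e-07, where the PC-3 level had fallen. Both depend on the pseudocount in size and possibly in sign, as untreated PC-3 was listed at 0. Neutrophil and monocyte chemokines responded more in THP-1 at 6 h (12 of 18 were higher and 2 were lower (12 and 3 adjusted over the list alone, 14 and 0 after scaling), adjusted p = 9.3e-15, or 0.016 with an estimated correlation).

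THP-1 responded more than SW620 in inflammatory cytokines at 3 h (12 of 26 were higher (12 and 1 adjusted over the list alone), adjusted p = 3.5e-22, or 0.0065 with an estimated correlation). It did so at 6 h too (13 of 26 were higher and 5 were lower (18 and 2 after scaling), adjusted p = 1.6e-14, or 0.015 with an estimated correlation). The same held for neutrophil and monocyte chemokines at 3 h (8 of 18 were higher and 1 were lower (11 and 0 after scaling), adjusted p = 4.0e-15, or 0.0072 with an estimated correlation) and at 6 h (13 of 18 were higher and 4 were lower (16 and 1 after scaling), adjusted p = 2.8e-20, or 0.0029 with an estimated correlation). Lymphocyte chemokines responded more at 6 h (3 of 9 were higher and 1 were lower (6 and 0 after scaling), adjusted p = 5.2e-06, or 0.0042 with an estimated correlation). So did mitochondrially encoded genes (13 of 13 were higher, adjusted p = 2.2e-25, or 0.015 with an estimated correlation). Single genes included TNF at 3 h (1.59, SE 0.20, adjusted p = 1.3e-05). CXCL10 at 6 h differed by 1.04, 2.13 after scaling, SE 0.18, adjusted p = 2.5e-05. Its direction is open, as fold changes are understated below 1 TPM (untreated SW620). The CXCL8 difference at 3 h was -0.10, 0.22 after scaling, SE 0.09, adjusted p = 0.45.

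PC-3 responded more than SW620 in interferon-stimulated genes at 6 h (39 of 75 were higher (43 and 2 adjusted over the list alone), adjusted p = 5.3e-54, or 0.027 with an estimated correlation). There, ISG15 differed by 0.97, SE 0.17, adjusted p = 4.4e-04 and OASL by 2.82, SE 0.14, adjusted p = 1.2e-12. At 3 h, inflammatory cytokines responded more in PC-3 (7 of 26 were higher, adjusted p = 2.7e-13, or 0.039 with an estimated correlation). Lymphocyte chemokines did as well (2 of 9 were higher (2 and 1 adjusted over the list alone), adjusted p = 3.0e-04, or 0.039 with an estimated correlation). CXCL8 differed by 1.23, SE 0.09, adjusted p = 1.9e-09 and NFKBIA by 0.74, SE 0.14, adjusted p = 8.4e-04. On GRCh38 with GENCODE 29 coordinates, the main genes lie at IFNB1 (chromosome 9, 21077105 to 21077963), IL6 (7, 22725884 to 22732002), CXCL8 (4, 73740506 to 73743716), CCL20 (2, 227805739 to 227817564), OASL (12, 121019111 to 121039242) and IFIT1 (10, 89392546 to 89406486).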

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

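The tests of the differences between responses, and those of abundant genes and transcript length for the fall of the median gene in THP-1, were planned; the other tests of explanations and the splits of the libraries were chosen only after the results were seen. For the splits between lines, the final scheme was chosen after the output of a first scheme had been seen. It exchanged line labels within each time after centring each line. A split that kept the real labels only before or only after treatment kept part of the real difference, so the splits are not a clean reference. Their counts are given, and chance is not called excluded. The results in the next 3 paragraphs drew attention because a test of the difference itself (limma, 3 libraries per group) found unequal responses in a pair of lines. Values in brackets are differences between log2 fold changes, the first line minus the second. In genes listed at 0 before and after treatment in a line they are the other line's own response, and mainly so below 1 TPM.

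THP-1 and PC-3 differed in the responses of 1189 of 13605 genes at 3 h and 7964 at 6 h (1088 and 3909 after scaling). The 3 h count was 245 over genes expressed in both lines, and 429 and 2109 with pseudocounts of 0.1 and 5. The 6 h count was 3771 with quantile normalization, 5157 after removal of the length and GC trends and 4554 without THP-1 6 h replicates 2 and 3. At 3 h, responses higher in THP-1 than in PC-3 were largest for CCL4L2 (3.09), SCHIP1 (2.79), CCL4 (2.72), C11orf96 (2.56), CCN2 (2.16) and MUC5B (2.13), with adjusted p from 3.6e-13 to 0.017. Responses lower in THP-1 than in PC-3 were largest for IFIT2 (-4.84), OASL (-4.31), IFIT1 (-4.28), IFIT3 (-3.35), ZC3HAV1 (-2.07) and RHOB (-1.95), with adjusted p from 8.5e-19 to 6.6e-08. MUC5B was listed at 0 in THP-1, and the SCHIP1 call was lost without PC-3 untreated replicate 1 (adjusted p = 0.068). At 6 h, responses higher in THP-1 than in PC-3 were largest for CCL4L2 (4.03), SNURF (4.01), CCL4 (3.26), CCL8 (2.94), IL36G (2.78) and TSLP (2.58), with adjusted p from 4.4e-15 to 7.1e-06. Responses lower in THP-1 than in PC-3 were largest for OASL (-6.37), IFIT1 (-4.71), IFI44 (-4.31), RSAD2 (-3.90), IFIT3 (-3.77) and IFIT2 (-3.73), with adjusted p from 7.5e-21 to 1.6e-13. CCL8, IL36G and TSLP were listed at 0 in untreated and 6 h PC-3. CCL4 and CCL4L2 had group means below 1 TPM there, and at 3 h these and C11orf96 did as well. CCL4 and CCL4L2 share reads, and SCHIP1 and SNURF share reads with overlapping genes. In the splits of the line labels at 3 h, at most 160 genes were called in another split (1 of 100 splits, the real one, reached its count). At 6 h 1 of 100 reached the real count as well, although another split called 5894 genes.

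THP-1 and SW620 differed in the responses of 1528 genes at 3 h and 9160 at 6 h (704 and 5518 after scaling). The 3 h count was 899 over genes expressed in both lines, 816 and 2318 with pseudocounts of 0.1 and 5, 752 with quantile normalization and 1016 after removal of the length and GC trends. The 6 h count was 4982 with quantile normalization. The 3 h count was 897 and 819 without SW620 untreated replicates 1 and 2, 975 and 820 without SW620 3 h replicates 2 and 3, 941 and 912 without THP-1 untreated replicates 2 and 3, and 935 and 954 without THP-1 3 h replicates 2 and 3. At 3 h, responses higher in THP-1 than in SW620 were largest for IFNB1 (2.74), CCL4L2 (2.64), ACOD1 (2.54), IL6 (2.51), CCL4 (2.43) and C11orf96 (2.21), with adjusted p from 1.2e-11 to 1.7e-06. Responses lower in THP-1 than in SW620 were largest for LOC102723553 (-2.21), CCDC194 (-1.59), IFIT2 (-1.59), ZNF516 (-1.53), ITIH4 (-1.43) and LRP1 (-1.41), with adjusted p from 2.4e-08 to 0.033. IFNB1, CCL4L2, ACOD1, IL6 and CCL4 were listed at 0 in untreated and 3 h SW620. The LOC102723553 call was lost after scaling (-2.08, adjusted p = 0.081). It was lost too without SW620 untreated or 3 h replicates 2 or 3, THP-1 untreated replicate 2 or THP-1 3 h replicates 1 or 3. Adjusted p was then 0.066 to 0.093. Reads of this gene can belong to near copies. At 6 h, responses higher in THP-1 than in SW620 were largest for CCL4L2 (3.58), IL6 (3.21), SNURF (3.14), CCL4 (2.96), CCL8 (2.94) and IDO1 (2.94), with adjusted p from 6.1e-14 to 5.2e-05. Responses lower in THP-1 than in SW620 were largest for OASL (-3.55), CSPG4 (-2.86), LOC102723553 (-2.70), ENG (-2.63), IFIT1 (-2.61) and ABCA1 (-2.55), with adjusted p from 6.3e-15 to 9.4e-04. CCL4L2, IL6, SNURF, CCL4, CCL8 and IDO1 were listed at 0 in SW620. Only the real split reached its count at 3 h (1 of 100 splits, highest other 0) and at 6 h (1 of 100), where another split called 8768 genes.

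PC-3 and SW620 differed in the responses of 2678 genes at 3 h and 1931 at 6 h (1444 and 1410 after scaling). The 3 h count was 1496 with a pseudocount of 0.1, 1299 with quantile normalization and 1420 after removal of the length and GC trends. The 6 h count was 858 with a pseudocount of 0.1 and 1167 over genes expressed in both lines. The 3 h count was 1715 without PC-3 untreated replicate 3, 1635 without PC-3 3 h replicate 1, 1784 without SW620 untreated replicate 2 and 1725 without SW620 3 h replicate 3. The 6 h count was 1201 without PC-3 untreated replicate 3, 1237 without PC-3 6 h replicate 1, 1285 without SW620 untreated replicate 2, and 1124 and 3269 without SW620 6 h replicates 1 and 2. At 3 h, responses higher in PC-3 than in SW620 were largest for OASL (3.69), IFIT1 (3.46), IFIT2 (3.25), IFNB1 (3.24), IFIT3 (2.76) and ACOD1 (2.46), with adjusted p from 1.2e-16 to 1.1e-09. Responses lower in PC-3 than in SW620 included MUC5B (-2.13), RGPD5 (-2.00), FBN2 (-1.96), FRMD4A (-1.92) and COL12A1 (-1.86), with adjusted p from 1.1e-11 to 0.0085. IFNB1, ACOD1 and FBN2 were listed at 0 in untreated and 3 h SW620, and IFNB1 also in untreated PC-3. At 6 h, responses higher in PC-3 than in SW620 were largest for RSAD2 (3.64), IFI44 (3.24), ACOD1 (2.97), OASL (2.82), ZC3HAV1 (2.65) and PMAIP1 (2.29), with adjusted p from 1.2e-12 to 1.1e-09. Responses lower in PC-3 than in SW620 were largest for MUC5B (-2.44), SCHIP1 (-2.42), FBN2 (-1.96), RGPD5 (-1.91), COL12A1 (-1.90) and COL4A2 (-1.88), with adjusted p from 1.9e-12 to 0.032. ACOD1 was listed at 0 in SW620. There MUC5B and COL12A1, at 3 h OASL, and at 6 h RSAD2, IFI44, SCHIP1 and FBN2 had means below 1 TPM. The SCHIP1 call was lost after scaling (-2.14, adjusted p = 0.076) and without PC-3 untreated replicates 1 or 3, or without PC-3 6 h replicates 1 or 2, or without SW620 untreated replicates 1, 2 or 3, or without SW620 6 h replicates 1 or 2 (adjusted p = 0.053 to 0.098), and the RGPD5 call without SW620 6 h replicate 1 (adjusted p = 0.051); RGPD5 shares reads with near copies. Only the real split reached its count at 3 h and 6 h (1 of 100 splits each, highest others 203 and 113).

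For comparisons of 3 libraries against 3, the 10 splits are too few for a share under 0.05 (1 of 10 each). The real and the highest other counts were 6366 and 1 for THP-1 at 3 h, 9936 and 0 at 6 h and 7840 and 1 between them, 8324 and 0, 8255 and 0 and 233 and 1 for PC-3, and 116 and 1, 2709 and 0 and 9 and 3 for SW620. Between untreated lines they were 11274 and 0 for THP-1 and PC-3, 11199 and 0 for THP-1 and SW620, and 10069 and 0 for PC-3 and SW620.

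The median gene in THP-1 fell at 6 h (log2 fold change -0.89). A few genes taking more of the counts could lower the rest, since 64 genes (ribosomal, mitochondrial and the 10 most abundant) held 20.5% of TPM before and 38.0% after. With these left out and the rest scaled to one sum, the median was -0.61 (-0.69 to -0.50 in the 6 h libraries), which argues against them as the whole cause. By length, the median was -0.67 in the shortest of 10 equal groups and -1.30 in the longest. Length was the median over annotated transcripts, however, and the large AHNAK counted as 584 nt. The shortest group can thus hold long mRNAs, so length bias as the whole cause could not be decided. Effects of L-pampo and time in medium stay open, as untreated cells were taken at 0 h alone. RNA breakdown or cell death stays open and was not tested.

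Fewer genes changed in SW620 than in PC-3 at 3 h. The median SD over the 3 groups was larger in SW620 (0.142) than in PC-3 (0.126) because of the 6 h libraries (0.177 against 0.123). At 0 h it was 0.0834 against 0.0830, and at 3 h 0.0880 against 0.118. The 6 h libraries also entered the spread used at 3 h. In 1 fit that gave each gene 1 variance for all lines, 243 genes changed in SW620 and 8093 in PC-3. This argues against spread as the whole cause. The authors' normalization is argued against by scaling, after which 100 genes changed in SW620 and 6577 in PC-3. As a hypothesis, low levels of TLR2 and TLR3 transcripts in SW620 could contribute, as TLR2 was lower there than in PC-3 by a log2 difference of 2.54. It stays untested at the protein level, and TLR3 held 1.04 TPM in PC-3.

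Between 3 h and 6 h in PC-3, 45 of 67 interferon-stimulated genes rose and 14 of 32 NF-kB targets fell, although the NF-kB list was not called with an estimated correlation (adjusted p = 0.0796). After removal of the length and GC trends, 48 interferon-stimulated genes rose and 16 NF-kB targets fell. This argues against these biases as the whole cause, as far as lengths taken as medians over annotated transcripts measure them. A signal from secreted interferon, whose IFNB1 transcript rose at 3 h, stays an open hypothesis and was not tested.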

How the results depend on the processing

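The settings with the length and GC trends removed, without both lower THP-1 6 h libraries (replicates 2 and 3, with the lone library assumed to vary like the other groups) and with scaling and no SW620 6 h replicate 2 were chosen only after the data had been seen; the others were planned. TPM values give no read numbers, so the depth and the sampling noise of each library are unknown and no count model was run. Of 326 counts of genes under other settings, 254 stayed within 1.5 times the reported count. Of 4325 results for lists, 3746 kept direction and side of the threshold, 301 were no longer past it, 111 newly past it, 129 moved and 38 turned. Of 12087 results for single genes, 11143 kept both, 620 were no longer past it, 79 newly past it, 162 moved and 83 turned. With an estimated correlation, 102 of 207 results for lists were no longer called. The cause was not tested, except where fewer libraries or genes were fitted or where fry, by construction, does not compare a list with other genes.

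For a pair of lines at one time, the number is that of genes whose responses differed. With quantile normalization, it was 3354 for THP-1 3 h, 4816 for THP-1 6 h against 3 h, 378 for PC-3 6 h against 3 h, 1282 for SW620 6 h, 3771 for THP-1 and PC-3 6 h, 752 for THP-1 and SW620 3 h, 4982 for THP-1 and SW620 6 h and 1299 for PC-3 and SW620 3 h. With median-of-ratios scaling, it was 3565 for THP-1 3 h, 5085 for THP-1 6 h against 3 h, 415 for PC-3 6 h against 3 h, 1570 for SW620 6 h, 3909 for THP-1 and PC-3 6 h, 704 for THP-1 and SW620 3 h, 5518 for THP-1 and SW620 6 h and 1444 for PC-3 and SW620 3 h. After removal of the length and GC trends, the number of genes was 3404 for THP-1 3 h, 4396 for THP-1 6 h against 3 h, 5407 for PC-3 3 h, 77 for SW620 3 h, 818 for SW620 6 h, 15 for SW620 6 h against 3 h, 5157 for THP-1 and PC-3 6 h, 1016 for THP-1 and SW620 3 h and 1420 for PC-3 and SW620 3 h. With a pseudocount of 5, it was 192 for SW620 3 h, 2109 for THP-1 and PC-3 3 h and 2318 for THP-1 and SW620 3 h. With a pseudocount of 0.1, it was 429 for THP-1 and PC-3 3 h, 816 for THP-1 and SW620 3 h, 1496 for PC-3 and SW620 3 h and 858 for PC-3 and SW620 6 h. Without a filter, it was 10 for SW620 3 h, 1437 for SW620 6 h and 16 for SW620 6 h against 3 h. With a filter at a TPM of 5, it was 219 for SW620 3 h. Without a mean-variance trend, it was 27 for SW620 3 h. With one fit over all 27 libraries, it was 243 for SW620 3 h and 20 for SW620 6 h against 3 h. With median-of-ratios scaling and no SW620 6 h replicate 2, it was 1363 for SW620 6 h and 5795 for THP-1 and SW620 6 h. With only genes expressed in both lines, it was 245 for THP-1 and PC-3 3 h, 899 for THP-1 and SW620 3 h and 1167 for PC-3 and SW620 6 h. Leaving out both lower THP-1 6 h libraries, the number of genes was 4554 for THP-1 and PC-3 6 h. Leaving out 1 library at a time, the number of genes was 4491 to 4902 for THP-1 3 h, 9361 to 10215 for THP-1 6 h, 6752 to 8803 for THP-1 6 h against 3 h, 7438 to 8212 for PC-3 3 h, 7332 to 8057 for PC-3 6 h, 162 to 272 for PC-3 6 h against 3 h, 3 to 12 for SW620 3 h, 511 to 4015 for SW620 6 h and 5 to 10 for SW620 6 h against 3 h. For the differences between lines it was 923 to 1209 for THP-1 and PC-3 3 h, 6932 to 8804 for THP-1 and PC-3 6 h, 10897 to 10972 for untreated THP-1 and PC-3, 819 to 1157 for THP-1 and SW620 3 h, 8646 to 9522 for THP-1 and SW620 6 h, 10882 to 10937 for untreated THP-1 and SW620, 1635 to 3086 for PC-3 and SW620 3 h, 1124 to 3269 for PC-3 and SW620 6 h and 9599 to 9645 for untreated PC-3 and SW620.

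Genes that turned direction after removal of the length and GC trends were, for THP-1 3 h, MAVS 0.14, TAP2 0.059, VSIR 0.17 and MYD88 0.090, and for THP-1 6 h, MAVS 0.21, NFKB2 0.20, VSIR 0.035, MYD88 0.59, TICAM1 0.23, IFIH1 0.48 and NFKBIA 0.48, and for PC-3 3 h, MAVS 0.048, TAP2 0.11, SLC7A11 0.19, CDC25B 0.018, PVR 0.10, MYD88 0.16 and TICAM1 0.049. For PC-3 6 h they were TAP2 0.057, HK2 0.050, VSIR 0.31 and MYD88 0.40, and for SW620 6 h, MAVS 0.082 and TAP2 0.058, and for THP-1 6 h against 3 h, C11orf96 0.18, TLE3 0.85, NKTR 0.21, CCDC194 0.70, MAVS 0.067, IRF5 0.54, CSF3 0.28, HELZ2 0.21, STAT2 0.51, PARP14 0.36, NLRC5 0.28, SNAI1 0.30, TNFSF9 0.16, MYD88 0.50, TICAM1 0.067, IFIH1 0.48 and ADAR 0.025. Genes that turned direction with median-of-ratios scaling were, for THP-1 3 h, TLR2 0.058 and MYD88 0.14, and for THP-1 6 h, TLR1 0.34, MYD88 0.56, IFIH1 0.51, NFKBIA 0.68 and TNFAIP3 0.17, and for PC-3 3 h, MYD88 0.17. For PC-3 6 h they were MYD88 0.38 and TNFAIP3 0.28, and for THP-1 6 h against 3 h, NKTR 0.18, CXCL2 0.0054, CSF3 0.15, STAT2 0.39, PARP14 0.30, NLRC5 0.0048, SNAI1 0.14, TLR1 0.42, MYD88 0.41 and IFIH1 0.55. Genes that turned direction with quantile normalization were, for THP-1 6 h, TLR1 0.094, MYD88 0.023, IFIH1 0.062 and CXCL8 -0.049, and for PC-3 3 h, CXCL16 0.12, TNFRSF14 0.022 and MYD88 0.078, and for PC-3 6 h, CXCL16 0.038, MYD88 0.28 and TNFAIP3 0.25. For THP-1 6 h against 3 h they were CCL4 -0.044, NKTR 0.23, CSF3 0.092, TNIP3 0.53, PARP14 0.093, SNAI1 0.18, TNFSF9 0.051, TLR1 0.31, IFIH1 0.34 and CXCL8 -0.084. Genes that turned direction without both lower THP-1 6 h libraries were, for THP-1 6 h against 3 h, TLE3 0.65 and IFIH1 0.24. Lists that turned direction in fry were, for THP-1 3 h, metallothioneins and NRF2 targets -0.0083, and for THP-1 6 h, co-stimulatory and checkpoint ligands -0.11, interferon-stimulated genes -0.50, metallothioneins and NRF2 targets -0.097 and NF-kB target and feedback genes -0.48, and for THP-1 6 h against 3 h, co-stimulatory and checkpoint ligands -0.22, G2 and M phase -0.27, inflammatory cytokines -0.36, interferon-stimulated genes -0.11 and TLR and RNA sensors and adaptors -0.48. For PC-3 3 h they were co-stimulatory and checkpoint ligands -0.26, G2 and M phase -0.28, metallothioneins and NRF2 targets -0.054, MHC class I antigen presentation -0.32 and TLR and RNA sensors and adaptors -0.34, and for PC-3 6 h, co-stimulatory and checkpoint ligands -0.25, G2 and M phase -0.23, glycolysis and hypoxia -0.29, metallothioneins and NRF2 targets 0.043 and NF-kB target and feedback genes -0.31, and for SW620 6 h, metallothioneins and NRF2 targets -0.0068. For THP-1 and PC-3 6 h they were metallothioneins and NRF2 targets -0.30 and NF-kB target and feedback genes -0.37, and for THP-1 and SW620 6 h, metallothioneins and NRF2 targets -0.16 and NF-kB target and feedback genes -0.52, and for PC-3 and SW620 3 h, TLR and RNA sensors and adaptors -0.14. Lists that turned direction with quantile normalization were, for THP-1 3 h, MHC class I antigen presentation -0.24, and for PC-3 3 h, mitochondrially encoded genes 0.010, and for PC-3 6 h, glycolysis and hypoxia -0.24 and mitochondrially encoded genes -0.040. For THP-1 and PC-3 3 h they were cytosolic ribosomal proteins 0.17, and for THP-1 and PC-3 6 h, G2 and M phase 0.015, and for THP-1 and SW620 6 h, G2 and M phase 0.095. For PC-3 and SW620 3 h they were mitochondrially encoded genes -0.021. Lists that turned direction among genes expressed in both lines were, for THP-1 and PC-3 3 h, neutrophil and monocyte chemokines -0.36, and for THP-1 and SW620 6 h, co-stimulatory and checkpoint ligands -0.41. The median of mitochondrially encoded genes, in SW620 at 3 h against 0 h, was -0.0072 and that of mitochondrially encoded genes, 6 h response differed between PC-3 and SW620, was -0.0027, both with quantile normalization.

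With the replicate number as a block, the number of genes was 6147 for THP-1 3 h, 9842 for THP-1 6 h, 7565 for THP-1 6 h against 3 h, 8421 for PC-3 3 h, 8391 for PC-3 6 h, 260 for PC-3 6 h against 3 h, 141 for SW620 3 h, 2572 for SW620 6 h, 10 for SW620 6 h against 3 h, 1122 for THP-1 and PC-3 3 h, 7938 for THP-1 and PC-3 6 h, 1418 for THP-1 and SW620 3 h, 9120 for THP-1 and SW620 6 h, 2684 for PC-3 and SW620 3 h and 1906 for PC-3 and SW620 6 h. No count moved beyond 1.5 times. Of the 27 correlations between libraries with one replicate number, after the group means were removed, none exceeded 0.10 (-0.13 to 0.07), so replicate number was not used for pairing.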

Other observations

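Genes shared between the lines were counted only after the results were seen. At 3 h, CCL20, CXCL1 and CXCL8 rose in all 3 lines. Among genes tested in both lines, 286 rose in THP-1 and PC-3 (expected 29.2 if calls fell independently), 3 in THP-1 and SW620 (expected 0.245) and 6 in PC-3 and SW620 (expected 0.492): CCL20, CXCL1, CXCL8, IFIT1, IFIT2 and OASL. After scaling, the 3 h counts were 1747 (expected 679), 22 (expected 6.35) and 29 (expected 9.87). The CXCL8 call in SW620 was lost without any 1 library. The IFIT1 and OASL calls there were lost in these fits too, which left CCL20, CXCL1 and IFIT2. After scaling, 22 genes rose in all 3 lines, including the interferon-stimulated IFIT1, IFIT2, IFIT3 and OASL, the NF-kB targets BIRC3 and TNFAIP3, and TIFA. Others were CDC123, GTF2A2, HMGN3, LLPH, MED21, NIP7, OSTC, PFDN4, PRDX3, RPL36AL and SNRPB2. At 6 h, 433 genes rose in THP-1 and PC-3 (expected 50.8), 167 in THP-1 and SW620 (expected 11.9), 207 in PC-3 and SW620 (expected 21.6) and 163 in all 3. After scaling, these counts were 2776 (expected 1187), 823 (expected 297), 849 (expected 294) and 795. The length trend was shared by the lines, so part of these overlaps can come from it.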
